A study of Rattus norvegicus with 60 samples.

How the data were processed

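Gene expression was measured in the prefrontal cortex and amygdala of male rats on a Sprague-Dawley background from selectively bred HR and LR lines at postnatal days 7, 14 and 21. There were 5 arrays per line, region and age, which makes 60 arrays in 12 groups. Per the labels, frozen brains were sectioned, stained neighbouring sections guided the dissection, and total RNA was converted to double-stranded cDNA and labelled with Cy3 in a one-colour NimbleGen reaction. The dissection text names only the amygdala for every sample, while the source field of the cortex samples names the prefrontal cortex dissected whole.

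The deposited values are normalized intensity on a linear scale, made by the authors with RMA per the submitters' processing notes, with no version given. The region tables had different distributions and different features. Whether they were normalized together is not given in the sources used here, so each region was fitted on its own and levels were not compared between regions. Each of the 30 columns of a region table equalled 1 column of its group in the deposited value table, so that table was not used as a separate source. The prefrontal cortex table held 18564 features after 1 control feature was left out, the amygdala table held 17519, and 15828 features were in both. The value table was empty for 1691 further features in the prefrontal cortex and 2737 in the amygdala, and the filter behind this is not stated. The genome build, slide and scan date were not given in the sources used here, so no slide or date could be fitted.

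The log2 of each intensity was taken here. The plan had assumed log2 values as deposited, and this step was added once the linear scale was seen. Array medians ran from 6.22 to 6.33 in the prefrontal cortex and from 5.94 to 6.17 in the amygdala on the log2 scale. No depth applies to intensities, and the number of arrays limits the precision. No 2 arrays of a region were identical among 435 pairs, where r ran from 0.758 to 0.967 in the prefrontal cortex and from 0.886 to 0.974 in the amygdala.

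Gene symbols were updated through the deposited gene ID or accession to the current rat reference, which was used for names only. This renamed 3494 features in the prefrontal cortex and 3280 in the amygdala, some of them deposited under provisional locus names. The plan had excluded provisional names, so some genes below could be named only through this update, and the deposited symbol is given for some of them.

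Each region was fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with the default prior) on its 6 group means, with 1 estimate of the spread per feature from its 30 arrays. The comparisons were HR minus LR at each age, the mean of these 3 differences, the F test of line by age interaction, and the change between ages averaged over the lines. The region comparison took the difference of the HR minus LR means of ages over the shared features, with all 60 arrays. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over all features of the table, and the threshold was an adjusted p under 0.05. Errors beside a log2 difference are the standard error of the limma fit, and those beside a group mean are the SD of its 5 arrays. For 1 gene with several features, the feature with the highest mean was used.

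Altogether 23 gene lists were fixed: DNA methylation and Polycomb machinery, histone deacetylases and acetyltransferases, glucocorticoid and stress peptides, serotonin, dopamine and noradrenaline signalling, GABA signalling and interneurons, glutamate receptors and synapse, growth factors and neurotrophins, immediate early genes, perineuronal nets and extracellular matrix, immature neurons and axon growth, proliferation, oxidative phosphorylation, astrocytes, oligodendrocytes and myelin, microglia and macrophages, major histocompatibility and interferon response, endothelium and pericytes, meninges and fibroblasts, choroid plexus and ependyma, blood, striatum, hypothalamus and thalamus, and male-linked genes as a check of the labels. The 22 lists with enough members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The male-linked list had 1 measured member, Sry, and was not tested as a list. Some genes stand in more than 1 list, such as Avp and Oxt among both stress peptides and hypothalamic genes.

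The genes named were set by rule. For the mean of the ages they were the 10 largest differences each way past the threshold with the same sign at all 3 ages. At each age they were the 5 largest each way, from P7 to P21 the 10 largest each way, and for the interaction and the region difference the 5 with the lowest p. Up to 4 members of each list with the lowest p could be named, and Dnmt1, Dnmt3a, Dnmt3b, Ezh2, Nr3c1, Crhr1, Fgf2, Bdnf and Htr1a always. Where nothing passed, the 5 lowest p are given as values. Nr3c1 is not analysed here, and 2 genes that the rule selected are not reported here. The comparisons, lists, rule for named genes and all alternatives except 5 were chosen before the data were examined.

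The alternatives set out beforehand were quantile normalization, median centring, leaving out dim features at 2 levels, 1 feature per gene, another variance prior, array weights, replicate number as a block, fits to the 10 arrays of an age, a threshold of 0.1, fry, an estimated list correlation, and leaving out each array in turn. The 5 alternatives chosen after the data were seen left out 2 amygdala P14 arrays that lay below the other P14 arrays on the age axis, 4 prefrontal cortex arrays with the widest residuals, or the 5 amygdala arrays of lowest median. They also took the code prefix in the column names as a random block or added the choroid plexus and blood list means as covariates. The 4 prefrontal cortex arrays left out were all from the HR line: P21 array 1, P14 arrays 2 and 5 and P7 array 2. Other groupings were drawn 100 times by shuffling line within age or age within line. Changes added to 200 features in simulated data were used to check the fit. With a log2 change of 1 in the mean of the ages, 98.5% were recovered in the amygdala and 89.2% in the prefrontal cortex, and at P21 alone 50% and 36.5%. In separate simulated data with no other change added, the choroid plexus and ependyma list, shifted by -0.5, was found in 10 of 10 draws in each region. Over those draws the preset correlation also called lists that had not been shifted, 8 in the prefrontal cortex and 1 in the amygdala, against 1 and 0 with the estimated correlation.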

Results

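The series profiled the prefrontal cortex and amygdala of young male rats from the HR and LR lines, which were bred for high and low locomotor response to an unfamiliar environment. The series title describes them as a model of differing anxiety and depression-like behavior. Pups were sampled at postnatal days 7, 14 and 21 (P7, P14 and P21), with 5 arrays for each line, region and age. Each value is a log2 intensity from a one-colour array. Arrays of the same group lay farther apart in the prefrontal cortex of HR rats, where the median SD of the brighter features was 0.509 to 0.596 by age, than in LR rats, where it was 0.353 to 0.409. In the amygdala it was 0.262 to 0.403 over both lines.

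In the amygdala, the HR line had far less signal than the LR line for Pmch, the precursor of melanin-concentrating hormone of the lateral hypothalamus, and for Folr1, a folate receptor abundant in choroid plexus. Averaged over the ages, HR minus LR was -2.33 ± 0.12 for Pmch and -2.02 ± 0.12 for Folr1 on the log2 scale (n = 15 arrays per line). At P21, Pmch was 6.28 ± 0.56 in HR and 9.37 ± 0.17 in LR amygdala (SD, n = 5). Also lower in HR were Nipsnap1 (-1.78 ± 0.11), the alpha-globin gene Hba-a3 (deposited as LOC287167, -1.70 ± 0.16), the neural progenitor factor Sox2 (-1.63 ± 0.11), Tspan18 (-1.54 ± 0.16) and Mrpl43 of the mitochondrial ribosome (-1.46 ± 0.08). Prr32 (-1.43 ± 0.12), the tubulin gene Tubb2b (-1.32 ± 0.11) and the chaperone gene Hspa8 (-1.31 ± 0.13) completed the 10 largest falls. For Pmch, Hba-a3, Sox2 and Mrpl43, each of the 15 HR arrays lay below every LR array of its age, and for Folr1 14 did.

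Higher in HR amygdala were Potem (deposited as LOC306365), with an HR minus LR difference of 1.65 ± 0.14, the transcription factor gene Hlf (LOC690286, 1.34 ± 0.17) and Avp, which encodes vasopressin (1.09 ± 0.11). The vomeronasal receptor gene Vom1r103 (1.16 ± 0.18), Ddx21-ps11 (1.15 ± 0.17) and Tmem150c (1.08 ± 0.16) were higher too. The kallikrein protease gene Klk7 (1.06 ± 0.16), Tafa1 (1.01 ± 0.14), Cyc1-ps1 (0.99 ± 0.21) and the keratin-associated gene Krtap10l2 (0.96 ± 0.15) were the other large rises. Of 17519 features, limma called 2618 after Benjamini-Hochberg adjustment, 1121 higher and 1497 lower in HR, with a median absolute difference of 0.50. The adjusted p was 2.05e-14 for Pmch, 2.37e-13 for Folr1, 2.97e-08 for Avp and 0.00112 for Cyc1-ps1, the highest among these 20 genes. With the choroid plexus and blood list means as covariates, an alternative chosen after the data were seen, 652 features were called, 430 higher and 222 lower. These list means differ between the lines themselves, so that fit also takes out line difference. With 1 feature per gene 1510 were called.

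**Figure D1:**
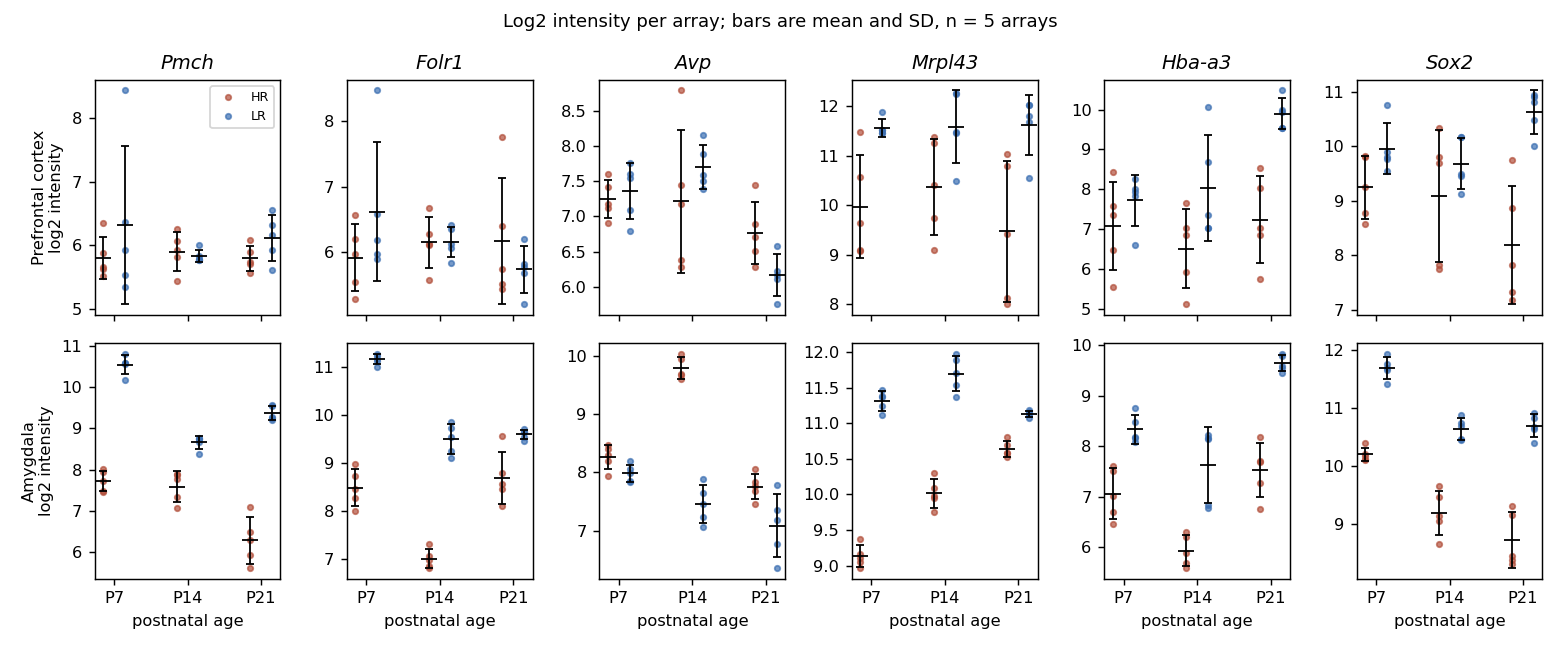
Log2 intensity (vertical axes) of 6 genes against postnatal age, one point per array, HR in red and LR in blue, with the mean and SD of 5 arrays. In the amygdala (lower panels) all 15 HR arrays lie below the LR arrays of the same age for Pmch, Mrpl43, Hba-a3 and Sox2, while Avp has HR means of 8.26, 9.78 and 7.76 and LR means of 7.99, 7.46 and 7.09. Among prefrontal cortex arrays (upper panels) none of these genes passed the test for the mean of the ages.

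Among the gene lists, choroid plexus and ependyma members were lower in HR amygdala. Of 13 measured members, 6 were lower and 0 higher for the mean of the ages, and the same numbers held when adjusted over the list alone (camera adjusted p = 0.00969, and adjusted p = 0.171 with an estimated correlation). Besides Folr1 these included the clotting factor gene F5 (-0.83 ± 0.11), Dynlrb2 of motile cilia (-0.89 ± 0.14) and the potassium channel gene Kcnj13 (-0.79 ± 0.16). Astrocyte genes were lower for 3 of 19 and higher for 0, the same adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.172 with an estimated correlation). These were S100b (-1.28 ± 0.09), Aldoc (-0.54 ± 0.08) and Gpr37l1 (-0.48 ± 0.11). Glucocorticoid and stress peptide genes were higher for 4 of 28 and lower for 0, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0396, and adjusted p = 0.172 with an estimated correlation). The 4 were Avp, the galanin gene Gal (0.68 ± 0.08), the oxytocin gene Oxt (0.79 ± 0.13) and the urocortin gene Ucn3 (0.47 ± 0.16).

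The other 19 lists did not shift as lists in the amygdala for the mean of the ages, although members of most passed on their own. Over all features 2618 of 17519 passed, so called members do not by themselves set a list apart. Oxidative phosphorylation genes were higher for 3 and lower for 8 of 44, or 5 and 11 adjusted over the list alone (camera adjusted p = 0.0832). The ATP synthase genes Atp5f1b (-1.05 ± 0.09) and Atp5f1a (-0.86 ± 0.11) were lower. Immature neuron and axon growth genes were lower for 4 of 21 and higher for 0, the same adjusted over the list alone: Tubb2b, Gap43 (-0.89 ± 0.10), Tubb3 (-0.83 ± 0.11) and Stmn1 (-0.45 ± 0.09) (camera adjusted p = 0.394). Microglia and macrophage genes were lower for 5 and higher for 2 of 17, the same adjusted over the list alone (camera adjusted p = 0.454). The complement genes C1qb (-0.64 ± 0.12) and C1qc (-0.61 ± 0.11) were lower and Tmem119 (0.54 ± 0.13) was higher. Of 9 blood genes, 4 were lower and 0 higher, the same adjusted over the list alone, among them the globin genes Hbb (-0.35 ± 0.07) and Hba-a2 (-0.35 ± 0.07) (camera adjusted p = 0.156). Of 13 meninges and fibroblast genes, 3 were lower, or 4 adjusted over the list alone, and 0 higher, led by Ptgds (-1.07 ± 0.12) and Col1a2 (-0.69 ± 0.11) (camera adjusted p = 0.207). Of 17 hypothalamus and thalamus genes, 2 were higher (Avp and Oxt) and 3 lower (among them Pmch and Calb2, -0.48 ± 0.11), or 2 and 4 adjusted over the list alone (camera adjusted p = 0.454).

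Of 25 DNA methylation and Polycomb genes, 4 were lower in HR amygdala and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.454). They were the methyl-binding gene Mbd3 (-0.83 ± 0.15), Apex1 (-0.25 ± 0.07), the de novo methyltransferase gene Dnmt3b (-0.46 ± 0.14, adjusted p = 0.020 by limma) and Rbbp7 (-0.33 ± 0.11). The difference was 0.02 ± 0.11 for Dnmt1, 0.01 ± 0.18 for Dnmt3a and 0.03 ± 0.15 for Ezh2, none past the threshold. Of 18 histone deacetylase and acetyltransferase genes, 1 was higher and 2 lower, or 2 and 3 adjusted over the list alone, with Hdac5 at -0.73 ± 0.08 (camera adjusted p = 0.454). Of 24 growth factor genes, 3 were higher and 2 lower, the same adjusted over the list alone, including Fgf2 (0.61 ± 0.19, adjusted p = 0.025 by limma) and its receptor gene Fgfr2 (0.50 ± 0.11) (camera adjusted p = 0.725). The stress receptor gene Crhr1 (0.09 ± 0.16), the neurotrophin gene Bdnf (-0.21 ± 0.14) and the serotonin receptor gene Htr1a (0.19 ± 0.15) did not pass. Of 20 serotonin, dopamine and noradrenaline genes 0 passed in limma over all features or adjusted over the list alone (camera adjusted p = 0.306), with the lowest p for Htr1d (0.35 ± 0.13).

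Glutamate receptor and synapse genes in the amygdala were higher for 1 (Grin1, 0.46 ± 0.13) and lower for 3 of 36, the same adjusted over the list alone, including Camk2b (-0.70 ± 0.10) and Gria2 (-0.65 ± 0.12) (camera adjusted p = 0.822). GABA and interneuron genes were lower for 2 of 23, Calb2 and Pvalb (-0.57 ± 0.14), and higher for 0, the same adjusted over the list alone (camera adjusted p = 0.602). Oligodendrocyte genes were higher for Mbp (0.46 ± 0.14) and lower for Cd9 (-0.39 ± 0.09) among 25, the same adjusted over the list alone (camera adjusted p = 0.602). Major histocompatibility and interferon genes were higher for 2 of 28, Ifi27 (0.58 ± 0.08) and B2m (0.21 ± 0.07), and lower for Psmb8 (-0.43 ± 0.12), the same adjusted over the list alone (camera adjusted p = 0.346). Among 12 endothelial and pericyte genes Cldn5 was lower (-0.87 ± 0.14, camera adjusted p = 0.822). Among 17 perineuronal net genes Timp2 was lower (-0.38 ± 0.08, camera adjusted p = 0.602) and among 12 striatal genes Ppp1r1b was higher (0.58 ± 0.16, camera adjusted p = 0.394). Each of these 3 lists had 1 call over all features and 1 adjusted over the list alone. Among 16 immediate early genes Jund was higher (0.47 ± 0.16), with 0 calls adjusted over the list alone (camera adjusted p = 0.602), and of 17 proliferation genes 0 passed in limma either way (camera adjusted p = 0.456). Sry, the measured male-linked gene, differed by 0.13 ± 0.15 and did not pass. The median, the mean and the test did not share a sign for the endothelial, glutamate, growth factor, immature neuron and immediate early lists.

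At P7, when rat pups are a week old, HR amygdala was lower in Tubb2b (-3.14 ± 0.20), Hspa8 (-3.05 ± 0.22), Tspan18 (-2.98 ± 0.28), Pmch (-2.82 ± 0.21) and Folr1 (-2.68 ± 0.20), with 5 arrays per line. The largest rises were those of Pax5 (1.40 ± 0.36), Mcee (1.40 ± 0.23), the odorant receptor gene Or10d5j (1.25 ± 0.28), the urotensin gene Uts2 (1.203 ± 0.329) and Cenpl (1.198 ± 0.265). Choroid plexus genes were lower for 6 of 13 and higher for 0, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.0946 with an estimated correlation). Meninges and fibroblast genes were lower for 5 of 13 and higher for 0, the same adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.0758 with an estimated correlation). Ptgds was at -2.12 ± 0.21 and the collagen gene Col1a2 at -1.63 ± 0.19. Hdac5 (-1.08 ± 0.14), Kat8 (-1.07 ± 0.20), Hdac4 (-0.92 ± 0.19) and Hdac2 (-0.80 ± 0.19) were lower as well. They were the 4 lower members of 18 histone deacetylase and acetyltransferase genes, with 0 higher and the same numbers adjusted over the list alone (camera adjusted p = 0.112). In limma, 1572 features passed, 438 higher and 1134 lower in HR. With the choroid plexus and blood means as covariates 368 passed, 191 higher and 177 lower.

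At P14, vasopressin and oxytocin messages stood out in HR amygdala: HR minus LR was 2.32 ± 0.20 for Avp and 1.52 ± 0.22 for Oxt (n = 5 per line). Hlf (2.52 ± 0.29), Zfp319 (2.25 ± 0.54), Aimp1-ps3 (1.91 ± 0.25) and the odorant receptor gene Or1o2e (1.83 ± 0.41) were also higher. Lower were Folr1 (-2.49 ± 0.20), the cilium gene Cfap126 (-2.14 ± 0.21), Prr32 (-1.85 ± 0.21), Hba-a3 (-1.70 ± 0.28) and Mrpl43 (-1.69 ± 0.13). Of 13 choroid plexus genes 5 were lower, or 6 adjusted over the list alone, and 0 higher (camera adjusted p = 0.001, and adjusted p = 0.0278 with an estimated correlation). Of 9 blood genes 3 were lower, or 4 adjusted over the list alone, and 0 higher, including Hbb (-0.48 ± 0.12) and Hbb-b1 (-0.47 ± 0.13) (camera adjusted p = 0.00267, and adjusted p = 0.0185 with an estimated correlation). In limma 967 features passed, 575 higher and 392 lower in HR, a balance that turned to 480 and 578 with median centring and 205 and 251 with 1 feature per gene. This count fell to 496 without LR arrays 4 and 5 (633 without array 5 alone), to 263 with the 10 arrays of this age alone, to 642 with replicate number as a block and to 104 with the choroid plexus and blood covariates.

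At P21, the amygdala differences were led by Potem (3.23 ± 0.24 higher in HR) and Pmch (-3.08 ± 0.21), with 5 arrays per line. The kallikrein gene Klk1c9 (2.24 ± 0.28), Tex35 (2.19 ± 0.26), the lectin gene Clec4m (2.18 ± 0.31) and Chi3l4 (2.09 ± 0.20) were higher. Nipsnap1 (-2.32 ± 0.19), Zfp319 (-2.25 ± 0.54), Hba-a3 (-2.12 ± 0.28) and Sox2 (-1.97 ± 0.19) were lower. Astrocyte genes were lower for 5 of 19 and higher for 0, the same adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.124 with an estimated correlation). S100b was at -1.26 ± 0.15, Gpr37l1 at -1.01 ± 0.19, the connexin gene Gjb6 at -0.94 ± 0.23 and Ntsr2 at -0.89 ± 0.23. Oxidative phosphorylation genes were lower for 5 and higher for 1 of 44, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.147 with an estimated correlation). Ndufv2 (-0.79 ± 0.18) and Sdhd (-0.56 ± 0.14) were among the lower ones. Dnmt3b was lower at this age (-0.85 ± 0.24, adjusted p = 0.0178 by limma), while Dnmt1 (0.20 ± 0.19) and Dnmt3a (-0.46 ± 0.31) did not pass. In limma 1686 features passed, 959 higher and 727 lower in HR, a balance that turned to 317 and 357 with 1 feature per gene (674 features). It also turned to 1498 and 1523 with array weights (3021 features) and to 877 and 911 without the dimmest features (1788 features at the stricter level). With the choroid plexus and blood covariates 1294 passed, of which 1178 were shared.

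Among genes that could be named, the 5 with the lowest p for line by age in the amygdala differed most between the lines at P7. The lowest adjusted p over all features was 1.96e-09, by the limma F test. Tubb2b went from -3.14 at P7 to -0.54 at P14 and -0.29 at P21 (HR minus LR), and Hspa8 from -3.05 to -0.45 and -0.43. The others were the chaperone regulator gene Ahsa1 (LOC681996; -2.13, -0.35 and -0.24), Tubb3 (-2.15, -0.78 and 0.44) and the peptide-processing enzyme gene Cpe (-2.48, 0.21 and -0.58). Their adjusted p ran from 4.22e-08 for Tubb2b to 5.49e-07 for Cpe. The limma F test of line by age passed for 1646 of 17519 amygdala features. It passed for 818 with 1 feature per gene and for 766 with the choroid plexus and blood covariates.

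In the prefrontal cortex, no gene passed the threshold for HR against LR. Averaged over the ages, genes of lowest p were Mrpl43 (-1.66 ± 0.31, adjusted p = 0.092 by limma), Hba-a3 (-1.61 ± 0.33, 0.146) and Sox2 (-1.25 ± 0.26, 0.146), and Ndufaf6 (-1.02 ± 0.24, 0.299) was also among the lowest. For Mrpl43, Hba-a3 and Sox2, 10 of the 15 HR arrays lay below every LR array of their age. Pmch differed by -0.26 ± 0.20 and Folr1 by -0.09 ± 0.23 in this region, where both were dim (means of 5.96 and 6.13, against array medians of 6.22 to 6.33). Both differences lean on LR P7 array 4, with Pmch at 8.43 (others of its group 5.34 to 6.36) and Folr1 at 8.46 (5.90 to 6.58). Oxidative phosphorylation was the list with a shift, with a median of -0.15 (camera adjusted p = 0.00356, and adjusted p = 0.758 with an estimated correlation). Of its 44 members 0 passed the threshold in limma over all features or adjusted over the list alone. The other 21 lists had a camera adjusted p from 0.45 to 0.902. Among the genes always reported, differences were -0.27 ± 0.36 for Dnmt1, 0.20 ± 0.15 for Dnmt3a, -0.06 ± 0.17 for Dnmt3b and -0.07 ± 0.16 for Ezh2. They were -0.06 ± 0.15 for Crhr1, 0.04 ± 0.31 for Fgf2, -0.13 ± 0.12 for Bdnf and 0.11 ± 0.11 for Htr1a.

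By age in the prefrontal cortex, the lowest p at P7 were those of the muscle gene Ky (-0.94 ± 0.20), Insl6 (-0.96 ± 0.22), Ess2 (-0.84 ± 0.20), Plppr1 (0.90 ± 0.22) and Cxxc4 (0.99 ± 0.25). At P14 they were those of Tnfaip8 (-1.41 ± 0.26), the steroid hydroxylase gene Cyp21a1 (-1.56 ± 0.32), Ankrd52 (-1.01 ± 0.22), Ddhd2 (0.78 ± 0.17) and Lrrc38 (0.99 ± 0.22). At P21 they were those of Sox2 (-2.44 ± 0.45), Spt1 (-1.37 ± 0.27), Supt5h (-1.13 ± 0.23), Hba-a3 (-2.66 ± 0.56) and Slitrk6 (0.84 ± 0.19). The oxidative phosphorylation list had a camera adjusted p of 0.0335 at P7 (adjusted p = 0.968 with an estimated correlation), with 0 of 44 members past the threshold in limma over all features or adjusted over the list alone. For the interaction, the lowest p belonged to Zfp771, whose HR minus LR values were 0.48, 0.67 and -0.90 at P7, P14 and P21, and to Insl6, Parm1, Spt1 and Ppp1r15a. The limma counts over 18564 features were 0 at P7, P14 and P21, 0 for the mean of the ages and 0 for the interaction. With an unadjusted p under 0.05 there were 896, 1017, 1458, 1303 and 1026 features, where chance would give 928. The lowest adjusted p were 0.864, 0.082, 0.114, 0.092 and 0.243. No alternative run gave more than 4 calls in any of these comparisons, and those 4 came with array weights at P21.

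**Figure D2:**
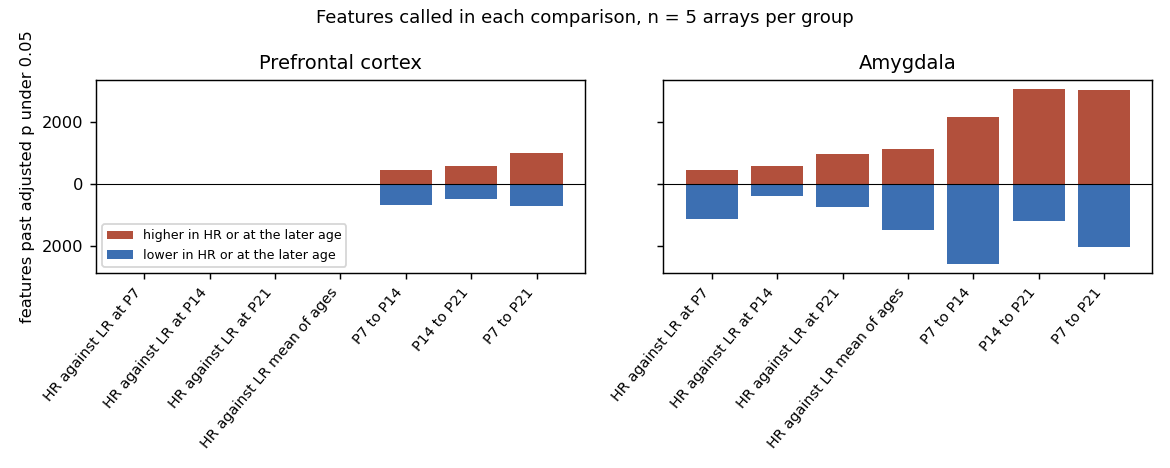
Number of features past an adjusted p of 0.05 (vertical axis, higher above 0 and lower below) in each comparison, for the prefrontal cortex (left, 18564 features) and amygdala (right, 17519 features), with 5 arrays per group. HR against LR gave 0 features in the prefrontal cortex at every age and 967 to 1686 in the amygdala, while P7 to P21 gave 1705 and 5102.

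The line difference itself differed between the regions for a small set led by Pmch. For Pmch, HR minus LR was -0.26 ± 0.20 in the prefrontal cortex and -2.33 ± 0.12 in the amygdala, a difference of 2.07 ± 0.23 (adjusted p = 3.19e-08 by limma). The prefrontal cortex value leans on LR P7 array 4, where Pmch was 8.43 (others of its group 5.34 to 6.36). Folr1 followed, with -0.09 ± 0.23 and -2.02 ± 0.12, a difference of 1.93 ± 0.26, then Tspan18 (1.45 ± 0.22) and Prr32 (1.42 ± 0.24), which were lower in HR in the amygdala. Prefrontal cortex levels of Pmch (5.96), Folr1 (6.13) and Tspan18 (6.14) lay below the array medians, which left little room for a fall there, and that of Prr32 was 6.71. Of 15828 shared features 40 passed in limma, 12 with a higher HR minus LR value in the prefrontal cortex and 28 with a lower one. These were 65 and 59 without the 4 prefrontal cortex arrays of widest residuals, which are all HR arrays. The count was 139 with array weights, 124 without the 4 prefrontal cortex arrays of widest residuals, 118 without HR P14 array 5 of that region and 14 with 1 feature per gene. Since no prefrontal cortex feature passed for the mean of the ages, limma called 0 features in both regions (1303 and 4699 had an unadjusted p under 0.05 in the separate regions).

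Across features, the amygdala line differences at different ages were weakly related. Pearson's r over features, which are not independent replicates, was 0.245 for P7 and P14, 0.149 for P7 and P21 and 0.180 for P14 and P21. The same 3 values in the prefrontal cortex were 0.121, 0.134 and 0.062, and the last turned to -0.200 without HR P14 array 5. These were 6 relations in 1 family, and groupings with the lines shuffled give their reference.

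From P7 to P21, the myelin protein gene Mobp was among the 10 largest rises of both regions. It rose by 3.41 ± 0.09 in the amygdala and 3.41 ± 0.39 in the prefrontal cortex on the log2 scale (n = 10 arrays per age and region). The muscle troponin gene Tnnc2 (3.98 ± 0.20 and 5.23 ± 0.51), Ppp1r14a (3.09 ± 0.16 and 3.02 ± 0.41) and Gsta1 (2.81 ± 0.14 and 2.76 ± 0.26) were also in this set. In the amygdala the largest rises included Apod (3.56 ± 0.21), Tmem125 (3.21 ± 0.19), the microglial protease gene Ctss (3.08 ± 0.11), Septin4 (2.89 ± 0.11) and Fn3k (2.86 ± 0.18). In the prefrontal cortex they included the interneuron genes Pvalb (3.55 ± 0.31) and Cort (3.199 ± 0.311), with Lynx1 (3.21 ± 0.28), Tesc (3.16 ± 0.27) and Ifi27l2b (2.76 ± 0.37).

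Ybx1, its pseudogene Ybx1-ps9 (LOC366068) and the tubulin genes Tubb5 and Tubb3 were among the 10 largest falls of both regions over the same 2 weeks. The change was -2.71 ± 0.10 in the amygdala and -4.17 ± 0.60 in the prefrontal cortex for Ybx1, and -2.61 ± 0.09 and -2.76 ± 0.38 for Ybx1-ps9. It was -2.81 ± 0.17 and -2.61 ± 0.48 for Tubb5 and -2.30 ± 0.13 and -2.44 ± 0.37 for Tubb3. The amygdala also showed falls of F13b (-3.43 ± 0.28), Cox6b2 (-2.91 ± 0.11), Tmem130 (-2.87 ± 0.19), RT1-M6-1 (-2.83 ± 0.30), Tubb2b (-2.50 ± 0.14) and Carm1 (-2.32 ± 0.19). The prefrontal cortex showed falls of Fnip2 (-3.19 ± 0.47), the growth cone gene Gap43 (-2.89 ± 0.47), Pafah1b3 (-2.83 ± 0.20), Bex4 (-2.79 ± 0.38), Rac3 (LOC688319, -2.76 ± 0.38) and Sox4 (-2.51 ± 0.34). In limma 5102 of 17519 amygdala features passed, 3049 higher and 2053 lower at P21, and 1705 of 18564 prefrontal cortex features, 1002 higher and 703 lower. With quantile normalization the prefrontal cortex numbers were 815 higher and 812 lower.

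Oligodendrocyte and myelin genes were higher at P21 for 15 and lower for 1 of 25 in the amygdala, the same adjusted over the list alone (camera adjusted p = 1.16e-08, and adjusted p = 0.00503 with an estimated correlation). Prefrontal cortex had 7 of 26 higher and 0 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.0972 with an estimated correlation). Oxidative phosphorylation genes were higher for 38 of 44 and lower for 0 in the amygdala, or 38 and 1 adjusted over the list alone (camera adjusted p = 5.27e-24, and adjusted p = 4.04e-06 with an estimated correlation). Ndufs3 rose by 1.53 ± 0.10, Ndufb9 by 1.52 ± 0.10 and Cox7a2 by 1.49 ± 0.08. Of the 44, 19 were higher in the prefrontal cortex, or 26 adjusted over the list alone, and 0 lower (camera adjusted p = 7.13e-11, and adjusted p = 0.0972 with an estimated correlation). Immature neuron and axon growth genes were lower for 11 and higher for 1 of 21 in the amygdala, the same adjusted over the list alone (camera adjusted p = 3.73e-08, and adjusted p = 0.000372 with an estimated correlation). Among 26 measured in the prefrontal cortex 8 were lower, or 12 adjusted over the list alone, and 0 higher (camera adjusted p = 1.37e-08, and adjusted p = 0.000274 with an estimated correlation).

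Astrocyte genes were higher at P21 for 8 of 19 in the amygdala, the same adjusted over the list alone, and 6 of 18 in the prefrontal cortex, or 9 adjusted over the list alone, with 0 lower in either. S100b rose by 2.001 ± 0.107 and 1.96 ± 0.42 and Ntsr2 by 2.64 ± 0.16 and 2.49 ± 0.27 (camera adjusted p = 0.00223 and 0.000113, and adjusted p = 0.0385 and 0.0406 with an estimated correlation). Microglia and macrophage genes were higher for 6 and lower for 3 of 17 in the amygdala, or 7 and 3 adjusted over the list alone. They were higher for 7 and lower for 0 of 17 in the prefrontal cortex, or 8 and 1 adjusted over the list alone. C1qa rose by 1.97 ± 0.11 and 1.62 ± 0.27 (camera adjusted p = 0.0436 and 0.000126, and adjusted p = 0.143 and 0.037 with an estimated correlation). Major histocompatibility and interferon genes were higher for 11 and lower for 1 of 28 in the amygdala, the same adjusted over the list alone. In prefrontal cortex 8 of 28 were higher, or 10 adjusted over the list alone, and 0 lower. B2m rose by 0.83 ± 0.08 and 1.49 ± 0.21 (camera adjusted p = 0.0436 and 0.000126, and adjusted p = 0.143 and 0.00409 with an estimated correlation).

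Blood genes rose for 5 of 9 in the amygdala with 0 lower, the same adjusted over the list alone, and for 5 of 9 in the prefrontal cortex with 1 lower, or 7 and 1 adjusted over the list alone. Hbb-b1 rose by 1.58 ± 0.09 and 1.21 ± 0.33, and the embryonic globin gene Hbe2 was the lower member in the prefrontal cortex (-0.78 ± 0.21). The blood list had a camera adjusted p of 0.00458 and 0.00102 (and adjusted p = 0.0127 and 0.117 with an estimated correlation). Proliferation genes fell for 5 of 17 in the amygdala and 4 of 24 in the prefrontal cortex, with 0 higher and the same numbers adjusted over the list alone. Ube2c changed by -1.16 ± 0.20 and -0.99 ± 0.23 (camera adjusted p = 0.0118 and 0.00434, and adjusted p = 0.0937 and 0.0591 with an estimated correlation). Glucocorticoid and stress peptide genes were higher for 6 and lower for 3 of 28 in the prefrontal cortex, or 7 and 3 adjusted over the list alone. They included somatostatin (Sst, 2.60 ± 0.32), cholecystokinin (Cck, 1.42 ± 0.17), neuropeptide Y (Npy, 1.33 ± 0.15) and corticotropin-releasing hormone (Crh, 1.15 ± 0.16) (camera adjusted p = 0.025, and adjusted p = 0.0406 with an estimated correlation). In the amygdala 8 were higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.947).

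Hypothalamus and thalamus genes fell for 7 and rose for 2 of 17 in the amygdala, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.0866 with an estimated correlation). Calb2 (-1.34 ± 0.14), Pmch (-1.31 ± 0.15) and Oxt (-0.87 ± 0.16) were among those that fell. The remaining lists did not pass, with camera adjusted p from 0.132 to 0.953 in the amygdala and from 0.155 to 0.996 in the prefrontal cortex. Among genes always reported, Bdnf rose in the amygdala and prefrontal cortex (0.92 ± 0.17 and 0.87 ± 0.15). Dnmt1 fell in the amygdala (-0.98 ± 0.14) and was -0.90 ± 0.44 in the prefrontal cortex, not past the threshold. Crhr1 fell in the prefrontal cortex (-0.59 ± 0.18) and was 0.27 ± 0.19 in the amygdala, not past it.

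**Figure D3:**
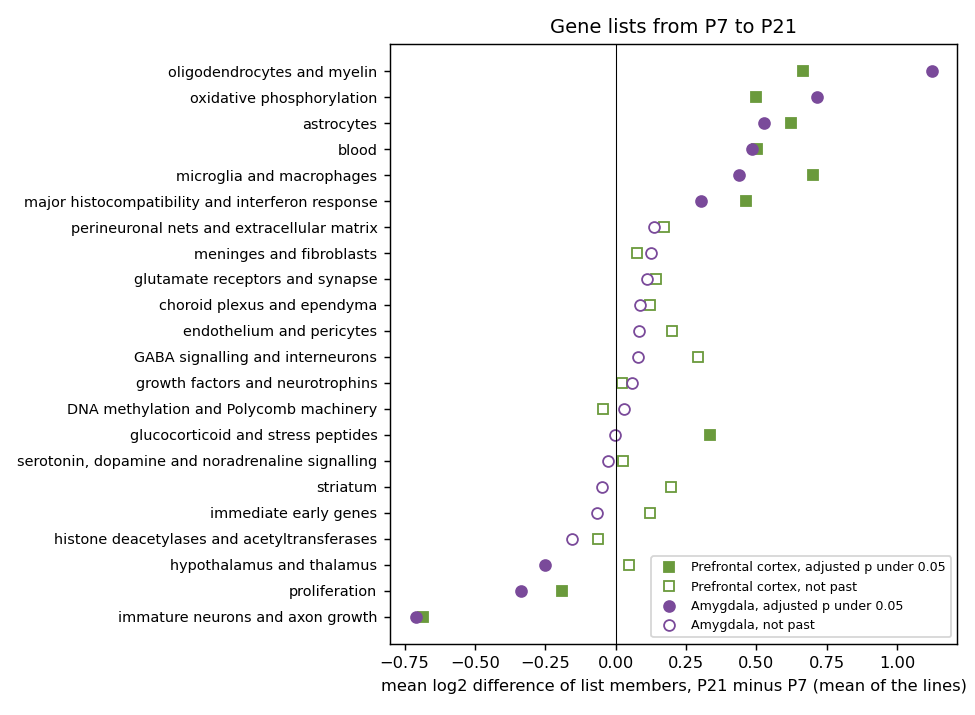
Mean log2 difference of the measured members of each of 22 gene lists between P7 and P21 (horizontal axis, P21 minus P7, averaged over the lines), in the prefrontal cortex (green squares) and amygdala (purple circles). Filled symbols passed camera at an adjusted p under 0.05 with the preset correlation, 9 lists in each region, of which 5 in each region also passed with an estimated correlation. The oligodendrocyte list lies highest in the amygdala (1.12) and the immature neuron list lowest (-0.71).

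From P7 to P14, immature neuron and axon growth genes were lower for 9 and higher for 2 of 21 in the amygdala, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.000482, and adjusted p = 0.0178 with an estimated correlation). Of 26 in the prefrontal cortex 6 were lower and 0 higher, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000551, and adjusted p = 0.0183 with an estimated correlation). Oxidative phosphorylation genes rose for 25 and fell for 9 of 44 in the amygdala from P7 to P14, or 26 and 10 adjusted over the list alone (camera adjusted p = 2.38e-09, and adjusted p = 0.00347 with an estimated correlation). Of the 22 lists 5 passed camera in each region over this week, 2 in the amygdala and 3 in the prefrontal cortex also with an estimated correlation. The other amygdala lists were oligodendrocytes (8 of 25 higher, 0 lower, adjusted p = 0.000807, estimated 0.116), histone deacetylases and acetyltransferases (6 of 18 lower, 0 higher, 0.0141, estimated 0.116) and proliferation (5 of 17 lower, 0 higher, 0.044, estimated 0.241). Adjusted over the list alone these were 8, 7 and 6. The other prefrontal cortex lists were microglia (4 of 17 higher, 0.00154, estimated 0.0559), stress peptides (3 of 28 higher, 0.00924, estimated 0.0183), major histocompatibility (1 of 28 higher, 0.00924, estimated 0.0317) and proliferation (3 of 24 lower, 0.0317, estimated 0.138). Adjusted over the list alone these were 5, 4, 1 and 5, and 0 members went the other way. In limma 4758 amygdala features passed, 2161 higher and 2597 lower, a balance that turned to 2225 and 1955 without the 5 amygdala arrays of lowest median. For the prefrontal cortex 1131 passed, 454 higher and 677 lower. That count was 676 without HR P7 array 4, 681 without LR P14 array 3, 751 without LR P14 array 5, 752 without HR P7 array 5 and 1718 with array weights.

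From P14 to P21, oligodendrocyte and myelin genes rose for 13 of 25 in the amygdala with 0 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 7.01e-05, and adjusted p = 0.0469 with an estimated correlation). Oxidative phosphorylation genes rose for 11 of 44 in the prefrontal cortex, or 18 adjusted over the list alone, with 0 lower (camera adjusted p = 2.95e-08, and adjusted p = 0.471 with an estimated correlation). In the amygdala 25 rose and 2 fell, or 26 and 2 adjusted over the list alone (camera adjusted p = 9.8e-07, and adjusted p = 0.0119 with an estimated correlation). The other amygdala lists past the threshold were astrocytes (11 of 19 higher, 1 lower, adjusted p = 0.00379, estimated 0.0503), blood (5 of 9 higher, 0 lower, 0.00258, estimated 0.0119) and hypothalamus and thalamus (3 of 17 lower, 1 higher, 0.0116, estimated 0.0469). The remaining prefrontal cortex list was astrocytes (1 of 18 higher, 0 lower, 0.0199, estimated 0.471). Adjusted over the list alone these had 11, 6, 3 and 2 members in that direction. In limma 4294 amygdala features passed, 3090 higher and 1204 lower, and 1054 in the prefrontal cortex, 577 higher and 477 lower. The prefrontal cortex balance turned to 536 higher and 575 lower with quantile normalization and to 261 and 304 with replicate number as a block within line. The prefrontal cortex count lay between 576 without HR P21 array 5 and 1824 without HR P14 array 2, and it was 1697 without the 4 arrays of widest residuals and 683 with 1 feature per gene.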

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

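The tests of uneven dissection and of less hypothalamic tissue, and every alternative that leaves out a chosen set of arrays or adds covariates, were chosen only after the results they bear on had been seen. The bound used to read the exchange of residuals between the regions was also changed after its value was seen, and shuffling line for Pmch and Folr1 replaced the within-group SD as the test of uneven dissection.

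In the amygdala, 1646 features had a line difference that itself differed between ages, by an F test, and for 40 of 15828 shared features the line difference differed between the regions. Other groupings of the same arrays, 100 for each result with the real one included, showed whether chance can be excluded. With line shuffled within age, only the real grouping (1 of 100) reached the amygdala counts of 1572 at P7 (highest other 9), 967 at P14 (336), 1686 at P21 (1164), 2618 for the mean of the ages (150) and 1646 for the interaction (349). The 3 shifted lists were likewise reached by 1 of 100 (highest other 2). Since 0 of them passed with an estimated correlation, chance is not excluded for the lists. Chance can be excluded for the feature counts above. The same held for the 40 features that differed between regions (1 of 100, highest other 1). The 5 counts of 0 in the prefrontal cortex were reached by all 100 groupings, and the 1 shifted list by 41 of 100 (highest other 4). Some of those groupings called many more features, up to 3 at P7, 1256 at P14, 11 at P21, 686 for the mean of the ages and 280 for the interaction. This points to a structure among the prefrontal cortex arrays, whose source was not tested. On an axis of change from P7 to P21 in this region, HR P14 arrays 1 and 2 lay at 0.831 and 0.802, among the HR P21 arrays (0.588 to 0.885). The other HR P14 arrays lay at 0.315 to 0.427. Whether these 2 arrays account for the structure was not tested.

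With age shuffled within line, the amygdala counts of 4758 from P7 to P14 (highest other 304), 4294 from P14 to P21 (1456) and 5102 from P7 to P21 (1) were each reached by 1 of 100 groupings, the real one. So were the prefrontal cortex counts of 1131 from P7 to P14 (64) and 1705 from P7 to P21 (104). The prefrontal cortex count of 1054 from P14 to P21 was reached by 2 of 100, the other with 1147. Chance can be excluded at this number of groupings for the amygdala counts and for the prefrontal cortex counts from P7 to P14 and from P7 to P21. For the prefrontal cortex count from P14 to P21, 2 of 100 was under the limit fixed beforehand for excluding chance. It is still not taken as excluded here, since another grouping called more features than the real one. For the correlations of line differences between ages, chance can be excluded in the amygdala for P7 with P14 (0.245, 1 of 100, highest other 0.161) and P7 with P21 (0.149, 1 of 100, highest other 0.105). It cannot be excluded for P14 with P21 (0.180, 6 of 100, highest other 0.247). For the prefrontal cortex 23, 21 and 45 of 100 groupings were as high as the real 0.121, 0.134 and 0.062, and the highest others were 0.439, 0.466 and 0.495. Chance cannot be excluded there.

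The HR against LR contrast called 2618 features in the amygdala and 0 in the prefrontal cortex (limma, 1303 with an unadjusted p under 0.05). When the residuals of the prefrontal cortex arrays were set on the amygdala group means of the shared features, the median count over 20 draws was 1340.5, with draws from 493 to 3649, against 2613 in the amygdala itself. The median count was thus below that of the amygdala, and every draw lay well above 0. Prefrontal cortex residuals can themselves add calls in single draws, since shuffled lines gave up to 686 there for the mean of the ages. How much of the gap wider spread between prefrontal cortex arrays accounts for therefore stays open. Keratin-associated and beta-defensin features, which brain tissue is not known for, were called for 22 of 60, all 22 higher in HR, against a median of 12 and a 95th percentile of 16 in matched random sets for the mean of the ages. By age, 2 were called at P7 (matched median 7), 8 at P14 (matched 95th percentile 8) and 22 at P21 (12). Part of the signal at P21 and in the mean of the ages may therefore come from outside brain transcripts, while the counts of this set at P7 and P14 did not pass the 95th percentile of its matched sets. Chemosensory receptor features passed theirs at P14 (28 called, 95th percentile 13), so such signal stays open at P14. They also passed it for the mean of the ages (47 called, 95th percentile 37). Krtap10l2 and Vom1r103, named above as higher in HR for that mean, and Or1o2e at P14 belong to these sets, so this limit applies to them. A difference between the lines in the amygdala remains an open biological explanation for the other calls, and slide or scan date cannot be examined with the sources used here.

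Pmch and Folr1 had the largest falls in HR amygdala, -2.33 and -2.02. At P14, Avp (2.323) and Oxt (1.522), which are abundant in hypothalamus, were higher in HR, where less hypothalamic tissue as a whole would lower them. These 2 genes were picked after their values were seen and can differ in their own expression, so they do not measure the amount of tissue. They also do not test a loss confined to the lateral hypothalamus, where Pmch is made. Over the 17 hypothalamus and thalamus genes the median at P14 was 0.025, with 2 higher and 1 lower. Avp (1.09) and Oxt (0.787) were higher for the mean of the ages too. Of the 17 hypothalamus and thalamus genes 3 were lower then, among them Pmch and Calb2. At P21 Avp (0.669) was higher past the threshold, and Oxt (0.295), Calb2 (0.278) and Prkcd (0.021) did not fall where Pmch fell by 3.08. Lhx2 of the list was lower at P21 (-0.678), and the list median was -0.193, with 1 member higher and 2 lower. Less hypothalamic tissue therefore stays open for the mean of the ages, at P14 and at P21. It stays open at P7, where Avp (0.272) and Oxt (0.545) did not pass while Calb2 (-1.342) and Prkcd (-0.671) of the same list fell with Pmch and Hcrt was at -0.875 without passing. Random unevenness of dissection from animal to animal is argued against: with line shuffled within age, the largest fall of any feature was -1.719 in the other relabellings of 10000, against -2.024 for Folr1 (permutation p = 1e-04, the smallest they can give). The test tried first did not decide it: the within-group SD lay at the 46.8th percentile of features of like level for Pmch and at the 71.4th for Folr1. Less choroid plexus stays open: within groups, over 30 arrays, Folr1 followed the other 12 choroid plexus members with r = 0.381 (permutation p = 0.115), Spearman's rho = 0.174 (permutation p = 0.467) and r = 0.075 without the 2 farthest arrays. A line difference in these genes and a dissection border set differently for the lines cannot be told apart, because the labels record no dissection details by sample.

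Single arrays lay far from the other 4 of their group in 13 of 132 groups of values checked, where about 1 in 20 is flagged by chance. In LR P7 prefrontal cortex array 4, the choroid plexus list mean was 7.15 (others 6.47 to 6.61), Folr1 8.46 (5.90 to 6.58), Sox2 10.76 (9.55 to 9.89) and Hba-a3 6.60 (7.82 to 8.26). The astrocyte list mean was 6.43 in HR P14 prefrontal cortex array 5 (others 6.85 to 6.98), and Pmch was 6.01 in LR P14 prefrontal cortex array 3 (5.77 to 5.83). Mrpl43 was 10.56 in LR P21 prefrontal cortex array 5 (11.67 to 12.03) and 11.89 in LR P7 prefrontal cortex array 5 (11.46 to 11.53). Amygdala array medians stood apart at 6.06 in HR P14 array 1 (others 6.14 to 6.16), 5.98 in LR P21 array 1 (6.13 to 6.15) and 6.11 in LR P7 array 4 (6.13 to 6.14). The choroid plexus list mean was 7.75 in HR P21 amygdala array 4 (others 7.24 to 7.37), and Pmch was 8.39 in LR P14 amygdala array 2 (8.67 to 8.78).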

How the results depend on the processing

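The fits with choroid plexus and blood covariates, with the code prefix as a random block, without the 4 prefrontal cortex arrays of widest residuals, without LR P14 amygdala arrays 4 and 5 and without the 5 amygdala arrays of lowest median were chosen after the results were seen. Of the values of comparisons over all alternatives, 783 stayed, 28 became weaker, 43 stronger, 2 moved and 5 reversed. A count of features was taken to stay if its size changed little, and its balance of higher and lower features was not compared. Some balances turned among those that stayed, such as that of the amygdala at P14 with median centring. For single genes 26943 stayed, 743 became weaker, 287 stronger, 172 moved and 5 reversed, and for gene lists 5856 stayed, 66 became weaker, 39 stronger and 1 reversed. No named gene past the threshold in the main fit or the altered one changed direction under quantile normalization or median centring. For named genes past it in neither fit, direction was not compared. A fit with the deposited value table was not run because its values were identical, and none with slide or scan date was run because neither is given. Median array levels were 5.94 to 6.33, and leaving out dim features at 2 levels gave 2654 and 2616 calls for the amygdala mean of the ages against 2618.

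For the prefrontal cortex, the 0 calls of HR against LR became 1 at P21 with quantile normalization, 1 for the mean of the ages with the trend and robust prior, and 4 at P21 and 1 for the mean with array weights. They became 2 and 2 with replicate number as a block within age, and 1 at P14 with only the 10 arrays of the age. They became 3 at P14 and 2 for the mean at an adjusted p under 0.1, and 3 at P14 and 1 for the mean without the 4 arrays of widest residuals. Features called in both regions accordingly went from 0 to 1 with the trend and robust prior, 1 with array weights, 2 with the replicate block, 2 at 0.1 and 1 without the 4 arrays. Leaving out single arrays gave 0 to 3 at P21, 0 to 2 for the mean and 0 to 2 for both regions. The cause was not tested.

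The prefrontal cortex age counts of 1131 and 1054 became 1718 and 1685 with array weights, 1700 and 1697 without the 4 arrays, and 744 and 565 with the replicate block within line, and 1054 became 683 with 1 feature per gene, where fewer features are tested. Leaving out single arrays gave 676 to 1534 and 576 to 1824. The correlation of P14 and P21 line differences in the prefrontal cortex reversed to -0.031 with 1 feature per gene and ran from -0.200 to 0.277 without single arrays. It was -0.017 without HR P21 array 2, -0.057 without HR P14 array 3, -0.200 without HR P14 array 5 and -0.026 without LR P14 array 4.

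In the amygdala, 1 feature per gene left 456 calls at P14, 674 at P21, 1510 for the mean and 818 for the interaction. The P14 count of 967 became 642 with the replicate block (616 shared), 263 with only the 10 arrays of the age, where fewer samples set the spread, 1470 at 0.1, and 496 without LR P14 arrays 4 and 5 (387 shared). It ran from 633 to 1023 without single arrays, the lowest without LR array 5. Array weights gave 3021 at P21. With the choroid plexus and blood covariates the counts were 368 at P7 (262 shared), 104 at P14 (55 shared), 1294 at P21 (1178 shared), 652 for the mean (464 shared) and 766 for the interaction (601 shared). These covariates also reversed the mean differences of Ahsp (0.181), Kcnj13 (0.019), Kat8 (0.010), Psmb8 (0.055) and Mgp (0.034), none of them past the threshold then. The choroid plexus and blood list means differ between the lines themselves (-0.373 and -0.129), so the fit takes line difference out of features that follow them. Kcnj13 is part of the choroid plexus mean, so its change was partly built in. The correlation of P7 and P14 line differences moved from 0.245 to 0.325 without the dimmer features. The cause of the other changes was not tested.

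The region difference of 40 became 14 with 1 feature per gene, 139 with array weights, 124 without the 4 arrays and 29 to 118 without single arrays. It was 118 without HR P14 array 5, 72 without HR P7 array 1 and 64 without HR P7 array 2, all in the prefrontal cortex. Of the 29 list shifts over the line comparisons and P7 to P21, 12 stayed past the threshold with an estimated correlation. With fry, which does not compare a list with other genes, 55 passed, and 26 to 31 passed without single arrays. Under fry the meninges list reversed from P7 to P21 in the amygdala (adjusted p = 0.024).

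The replicate block took arrays of the same number as linked. The numbers do not pair the samples: across lines within an age, residuals of arrays with the same number correlated from -0.020 to 0.031 in the amygdala and from -0.073 to 0.303 in the prefrontal cortex. The array of the same number was the closest in 1 and 3 of 15 cases. As a random block, the code prefix in the column names had a correlation of -0.011 in the prefrontal cortex and -0.027 in the amygdala over 16 blocks, and line, age and number across the regions had 0.003.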

Other observations

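The tests of a correlation between regions at P21 and of chemosensory receptor genes were chosen after those results had been seen. The own-region age axis was also looked at before any test of it was written, and the axis of the other region was set aside as a test after its values were seen.

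Mrpl43, Hba-a3 and Sox2 differed between the lines by like amounts in both regions. HR minus LR for the mean of the ages was -1.66 and -1.46 for Mrpl43, -1.61 and -1.70 for Hba-a3 and -1.25 and -1.63 for Sox2 in the prefrontal cortex and amygdala. These passed the threshold in the amygdala alone, and the regions were not shown to differ for these 3. Other genes past the threshold for the region difference, outside the 5 of lowest p and chosen after their values were seen, were Tnfrsf1b (-0.62 and 0.69), Yipf5 (0.43 and -1.06), Avp (0.00 and 1.09), Tafa1 (-0.24 and 1.01) and Zfp36l2 (0.44 and -0.52).

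At P21 the line differences of the 15828 shared features correlated between the regions with r = 0.355, against 0.036 at P7 and 0.041 at P14, over features that are not independent replicates. For the mean of the ages r was 0.336. Over the 2540 shared features called in the amygdala for that mean r was 0.54, and 1830 of them (72%) had the same sign in the prefrontal cortex. The values for the mean were not tested by relabelling. The codes in the column names match between the regions for 9, 9 and 10 samples at P7, P14 and P21, so the regions may come from the same animals, in which case the differences between regions are not independent. When line was shuffled over the P21 samples coded alike, 1 of 100 groupings, the real one, reached 0.355, and the highest other reached 0.341. P21 was picked for this test after the values at P7, P14 and P21 had been seen, with no allowance for that choice. Chance is therefore not taken as excluded for this correlation. Array residuals of samples coded alike had a median correlation of 0.002 over 28 pairs.

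One hypothesis was that HR amygdala lies earlier on a developmental axis at P21. On the axis from P7 to P21 of its own region, HR arrays averaged 0.845 ± 0.058 and LR arrays 1.017 ± 0.039 (SD, n = 5, two-sided exact permutation p = 0.00794, adjusted p = 0.0476 over 6 tests). Prefrontal cortex arrays averaged 0.778 and 0.961 (exact permutation p = 0.0317, adjusted 0.0794). In the other 4 tests HR minus LR was -0.051 at P7 (exact permutation p = 0.0397, adjusted 0.0794) and 0.078 at P14 (0.317, adjusted 0.333) in the amygdala. It was 0.157 at P7 (0.151, adjusted 0.226) and 0.129 at P14 (0.333, adjusted 0.333) in the prefrontal cortex. HR amygdala arrays thus averaged lower at P7 too, though not past the threshold after adjustment, and not at P14. On the axis from P7 to P14 of the other region HR amygdala arrays lay higher at P21, at 0.188 against -0.087 (exact permutation p = 0.00794, the smallest that 5 against 5 can give), and also at P7 (0.162 against -0.162) and P14 (0.498 against 0.308). This axis was made without P21 and placed P21 below P14 in both regions, so it did not order the ages, which leaves slower change with age in the HR line open. Weaker signal of bright features in HR arrays stays open as well, since features that fall with age in the prefrontal cortex were higher in HR by 0.085 (SD of relabelled values 0.065, exact permutation p = 0.159). Of 3 ways tried, 1 passed 0.05 in that direction.

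In the amygdala, chemosensory receptor genes were called for 47 of 348 features for the mean of the ages, 45 higher and 2 lower in HR, against a median of 29 and a 95th percentile of 37 in matched random sets. By age they were called for 8 at P7 (matched median 16), 28 at P14 (median 9, 95th percentile 13) and 36 at P21 (17.5 and 24.05), so the P7 count lay below the matched median. On the age axis of their own region, LR P14 amygdala arrays 4 and 5 lay at 0.361 and 0.354, the other P14 arrays at 0.528 to 0.631 and the P7 arrays at 0.034 to 0.139. In the prefrontal cortex, HR P14 arrays 1 and 2 lay at 0.831 and 0.802, within the HR P21 range of 0.588 to 0.885. The P14 to P21 count of that region was 1779 without HR P14 array 1 and 1824 without HR P14 array 2, against 1054.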
